A study of Mus musculus with 13 samples.

How the data were processed

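Bulk RNA was measured in 9 libraries of sorted interfollicular basal keratinocytes (CD49f positive, CD34 negative) from abdominal skin of C57BL/6 mice: 3 of wild type (WT) mice at gestation day 16 (dpc16), 3 of non-pregnant (NP) WT mice and 3 of Tbx3 conditional knockout (cKO) mice at dpc16. The cKO mice carried K14creERT2, a tamoxifen-inducible recombinase driven by the keratin 14 promoter, and floxed Tbx3 alleles. The part of Tbx3 that recombination removes, and whether the WT mice of the bulk libraries received tamoxifen, are not given in the sources used here. Single-cell libraries came from whole epidermis of tamoxifen-treated Tbx3creERT2; R26H2B-EGFP mice in 4 states, with 1 library each: NP, dpc16, and days 6 and 40 post partum (dpp6, dpp40). Skin was dissociated with trypsin at 37 °C, per the labels' protocols. Bulk libraries were made with a stranded mRNA kit from RNA with an integrity number above 7, and all libraries were sequenced on an Illumina NextSeq instrument, per the labels' protocols.

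The authors deposited bulk values as FPKM (fragments scaled by transcript length and by library size) in 1 table of 21950 genes. The submitters' processing notes name cutadapt 1.14, TopHat2, Cufflinks 2.2.1, Cuffdiff and the mouse build mm10 without giving their roles or order. The annotation release, the strand setting and any scaling between libraries are not given in the sources used here, and the sequencing depth behind the FPKM is unknown. The deposited single-cell files hold raw UMI counts (unique molecular identifiers) per gene and barcode, with 28693 genes including an added EGFP gene. Per the submitters' processing notes Cell Ranger 2.2.0 was used, and the barcodes had already been filtered to cells by a rule that is not given. The table's columns carry a group name and a number. The columns headed WT were taken as the dpc16 group, because the other headings name the NP and cKO groups. Libraries are numbered here by column order, and that number was not assumed to equal the replicate number in the sample titles.

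Gene IDs without version numbers were matched to GENCODE release M21 of the mm10 assembly (GRCm38) for positions, which found 21886 of the 21950 IDs. A total of 23 symbols belonged to more than 1 ID, and these were kept apart by ID. Values were taken as log2(FPKM + 1), a scale that understates changes of genes with low FPKM. The 11497 genes with a mean of at least 1 FPKM over the 9 libraries were tested with limma 3.58.1 in R 4.3.3: a fit of 3 group means over all 9 libraries, empirical Bayes moderation with a trend, two-sided tests, and Benjamini-Hochberg adjustment with a threshold of 0.05. The contrasts were WT dpc16 against WT NP, Tbx3 cKO dpc16 against WT dpc16, and, as a secondary one, Tbx3 cKO dpc16 against WT NP. The labels do not say that the libraries of a group came from separate animals, so p-values measure only the spread between libraries, which may be technical.

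A set of 37 gene lists (cell type markers, cell cycle, signalling, hormone, matrix, stress and metabolic genes) was tested with limma's camera at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the 32 lists with enough tested members. The same lists were tested with camera's estimated correlation and with fry, whose p-value asks whether a list's genes move one way on balance. The genes named in the text followed a fixed rule. After Tbx3, it took the 12 largest rises and 12 largest falls among genes past the threshold, with a mean of at least 5 FPKM over the 6 libraries compared and no overlap between the groups. It took 5 each way for the secondary contrast. From each list past the camera threshold, or with 3 or more members past the threshold, the 4 members with the smallest p were named, and from any other list at most 2. Some genes that the rule names are not reported here. The lists, the naming rule, the contrasts, the tests, the filters and most alternatives were set before the data were examined.

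Reversal of the pregnancy changes in cKO was measured across genes by the correlation and covariance of the contrasts WT dpc16 minus NP and cKO minus WT dpc16. These share the WT dpc16 libraries with opposite sign, which alone gives a negative value. The observed values were therefore set beside 100 simulated data sets of 9 libraries with no group effect and each gene's own residual spread. A moderated spread had been used first, and the residual spread was chosen after that result was seen.

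For single cells, barcodes with at least 200 genes and at most 10% mitochondrial UMIs were kept. Scrublet as built into scanpy 1.11.5, with an expected rate of 6%, placed no barcode of any library above its own threshold, so no doublets were removed. Cells of the 4 libraries were clustered together on 2000 variable genes, 30 principal components and 15 neighbours with the Leiden method (leidenalg 0.10.2, resolution 1), without integration of libraries, in Python 3.11.15 with seed 1. The 25 clusters were named from the fixed marker lists of 17 classes. The naming rule was settled after the clusters had been seen: markers were compared with the other clusters at a pseudocount of 100 CPM (UMIs scaled to a common total; 4 values were tried). A cluster took the class with most markers among its 10 leading genes, if at least 3 of the class markers lay above a log2 difference of 0.25 and no other class present among those 10 had a higher mean. A cluster with no marker among its 10 leading genes, as cycling ones can have, took the class of highest mean, if that mean was above 0.25 and at least 3 markers lay above 0.5. A total of 6 clusters stayed unnamed and 4 were called basal-like. UMIs were summed per library over basal-like cells as CPM with exact 95% Poisson intervals, and changes were taken as log2 of CPM plus 5. Shares of cells carry exact Clopper-Pearson 95% intervals. All such intervals cover counting error only, because each state has 1 library, and no p-value was computed between states.

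Cells were thinned to 2000 UMIs before counting cells with a Tbx3 UMI or with at least 3 UMIs of the G2/M list, so that depth did not set the share. A list's median change was placed among 10000 random lists of the same size drawn from 20 bins of mean expression. The named single-cell genes were the 10 largest rises and falls of dpc16 against NP and the 6 largest of each other comparison. They had at least 50 CPM in the higher library and intervals that did not overlap. Mitochondrial, haemoglobin and ribosomal protein genes and Xist were left out. After the clusters had been seen, the 34 genes that lead the basal-like clusters (the top 10 of each) were left out as well. Lists used genes with a mean of at least 5 CPM over the 4 libraries. The agreement with bulk used genes with at least 20 CPM in the higher of the NP and dpc16 libraries.

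The test was checked on repeated simulated sets of 11497 genes, with 250 changes of each size in all. In the WT dpc16 against NP comparison limma recovered 6% of changes of 0.58 (log2), 44% of 1, 92.8% of 2 and 99.6% of 3. The false share of calls there was 4.72%. The simulated noise was independent between genes and took the spread of the fit itself, so these shares do not cover correlation between real genes. For cKO against WT dpc16 the recovered shares were 6.4%, 48%, 90% and 98.4% with 4.86% false, and for cKO against NP they were 6.4%, 42%, 94% and 97.2% with 4.92% false. In simulated single-cell sums over 2162 genes, intervals lay apart in the right direction for 94% of 50 genes changed by 0.58 and for 100% of those changed by 1, 2 or 3.

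Alternatives covered pseudocounts of 0.1 and 5 FPKM, no filter on low values, a filter of 5 FPKM, quantile normalization, equalised medians of log ratios, moderation without a trend or with robust settings, a fit of the 6 libraries compared alone, a 2-fold minimum, and leaving out each of the 9 libraries in turn. For single cells they covered the clustering resolution, the mitochondrial limit, thinning depth, UMI minimum, pseudocount, CPM minimum, per-cell means and cells used. Keeping doublets equals the main analysis, since none were called. A block by column number, removal of the top 6% of doublet scores, other naming pseudocounts, cluster 5 counted as basal-like, G2/M shares over all cells of a library, and both other spreads for the reversal were added after the data had been seen. The title number of each bulk sample could not be assigned to a column, so the planned block by title number was not run. Numbers were computed with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and scikit-learn 1.9.0, and figures with matplotlib 3.10.9. Raw reads were not analysed here.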

Results

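Gene expression was measured in mouse abdominal epidermis before, during and after pregnancy, in 9 bulk libraries of sorted interfollicular basal cells and 4 single-cell libraries of whole epidermis. The bulk libraries fall into 3 groups of 3: WT at gestation day 16 (dpc16), WT non-pregnant (NP) and Tbx3 conditional knockout (cKO) at dpc16. The table heads the dpc16 columns only as WT, so they were identified by exclusion. Summed FPKM lay between 785636 and 847693 per library, the 10 highest genes took 10.4% to 13.7% of it, and 11212 to 11604 genes reached 1 FPKM. The single-cell libraries held 40450455 (NP), 74804602 (dpc16), 56849153 (day 6 post partum, dpp6) and 63492242 UMIs (day 40 post partum, dpp40).

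Tbx3, a T-box transcription factor and the targeted gene (ENSMUSG00000018604; mm10 chromosome 5, 119670669 to 119684724), was measured first in every bulk library. The 3 WT dpc16 libraries held 16.96, 15.29 and 22.98 FPKM of Tbx3, the 3 NP libraries 8.96, 6.38 and 8.12, and the 3 cKO libraries 4.81, 1.65 and 4.89. Every cKO library lay below every other library, so the labels and the Tbx3 values go the same way. The deleted part of the gene is not stated, so FPKM over the whole gene can include reads from exons that remain. Tbx3 fell in cKO against WT dpc16, with a log2 change of -2.09 and a limma Benjamini-Hochberg adjusted p of 0.0124. Without WT dpc16 library 3 that adjusted p was 0.0626, and without the filter on low FPKM 0.0511, in a range of 0.00875 to 0.0626 over its alternatives. In WT dpc16 against NP Tbx3 stood at 18.4 ± 4.05 against 7.82 ± 1.32 FPKM (SD, n = 3 each), a log2 change of 1.13 (SE 0.31) that did not pass (limma with Benjamini-Hochberg, adjusted p = 0.258).

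The comparison of WT dpc16 with WT NP asks how pregnancy changes basal keratinocytes. Pyy, a peptide hormone best known from the gut, rose from 33.3 ± 8.42 to 245 ± 56.1 FPKM (SD, n = 3 each), and Tgm3, a transglutaminase that crosslinks the cornified envelope, from 13.3 ± 7.69 to 110 ± 2.82. Fkbp5, a co-chaperone of steroid receptors, rose from 6.26 ± 1.30 to 46.2 ± 9.20 FPKM. Angptl4, a secreted inhibitor of lipoprotein lipase, rose from 5.33 ± 1.31 to 35.1 ± 8.53, and Prlr, the prolactin receptor, from 7.44 ± 1.18 to 27.7 ± 1.95. Pkib, an inhibitor of protein kinase A, fell from 105 ± 19.3 to 27.6 ± 12.3 FPKM, and Unc13b, a vesicle priming factor, from 12.1 ± 1.03 to 4.29 ± 0.282.

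By limma with Benjamini-Hochberg adjustment, 15 of 11497 genes passed between WT dpc16 and NP, 12 higher and 3 lower, against 1040 at an unadjusted p under 0.05. The groups did not overlap for 15.6% of genes, where chance gives 10%. Large log2 changes were 3.23 for Drc1, a ciliary dynein regulator (SE 0.48, adjusted p = 0.0412), 3.15 for Tgm3 (SE 0.42, adjusted p = 0.0252) and 3.07 for the serpin Serpina3b (SE 0.34, adjusted p = 0.00683). Pyy rose by 2.85 (SE 0.26), Fkbp5 by 2.70 (SE 0.24) and Angptl4 by 2.51 (SE 0.23), each with an adjusted p of 0.00242, and Prlr by 1.77 (SE 0.18, adjusted p = 0.00411). Deptor, an inhibitor of mTOR kinase, rose by 1.75 (adjusted p = 0.0150), Il4ra, the interleukin 4 receptor chain, by 1.72 (adjusted p = 0.0347) and Xdh, xanthine dehydrogenase, by 0.90 (adjusted p = 0.0413). Pkib had a log2 change of -1.96 (SE 0.28, adjusted p = 0.0347) and Unc13b of -1.30 (SE 0.18, adjusted p = 0.0313). For each of these genes all 3 dpc16 libraries lay on 1 side of all 3 NP libraries. The last riser, Grk3, a receptor kinase, stood at 5.79 ± 1.26 against 0.531 ± 0.350 FPKM (log2 2.16, adjusted p = 0.0252). Grk3 lies outside the naming rule and is named after its values were seen. Reads of Serpina3b can be shared with its paralogs, so its value is uncertain.

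Calls for Pyy, Fkbp5, Angptl4 and Prlr held when any 1 library was left out. Several others did not: without WT dpc16 library 1 the adjusted p was 0.117 for Tgm3 (0.0126 to 0.117 over its alternatives), 0.0933 for Deptor (0.00922 to 0.0933), 0.223 for Drc1 (0.0110 to 0.223) and 0.197 for Il4ra (0.0129 to 0.197). Without WT dpc16 library 2 it was 0.193 for Unc13b (0.0124 to 0.193) and 0.271 for Xdh (0.0278 to 0.271), and without NP library 2 it was 0.140 for Pkib (0.0170 to 0.140). Xdh lost its call in all 9 leave-one-out fits, Pkib in 8, Unc13b, Drc1 and Il4ra in 7 each, and Tgm3 and Deptor in 4 each. Serpina3b missed the threshold without NP library 3 (0.0721, in a range of 0.00204 to 0.0721). Grk3 was not followed by name over the alternatives. Without WT dpc16 library 1, 2 or 3, NP library 1, 2 or 3 or cKO library 1, all calls shared with the main fit were rule-named genes. Grk3 therefore lost its call in each of those fits. The count of 15 became 6 without WT dpc16 library 1, 9 without library 3, 8 without NP library 2, 5 without NP library 3 and 8 without cKO library 1. It was 9 without the filter on low FPKM.

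**Figure D1:**
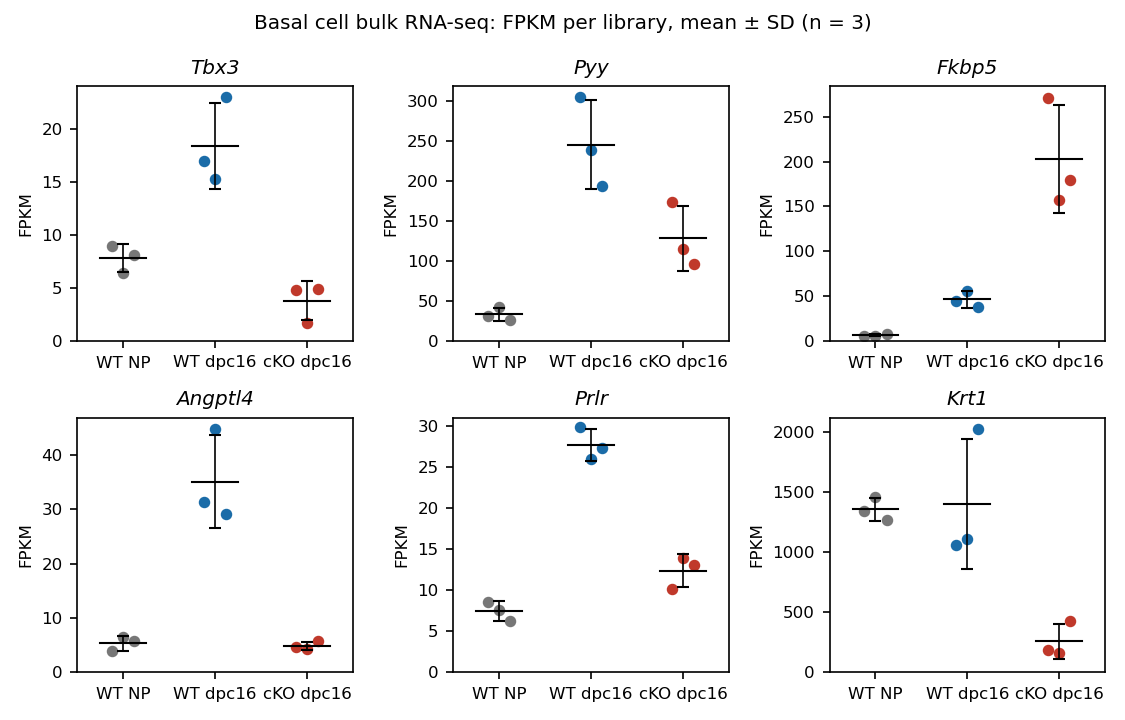
FPKM of named genes in the 3 WT NP, 3 WT dpc16 and 3 Tbx3 cKO dpc16 bulk libraries, with points for libraries and the mean with its SD. Tbx3 means are 7.82, 18.4 and 3.78 FPKM in that order.

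On mm10, Tgm3 (ENSMUSG00000027401) lies on chromosome 2 from 130012349 to 130050399, and Pyy (ENSMUSG00000017311) on chromosome 11 from 102106676 to 102107832. Fkbp5 (ENSMUSG00000024222) lies on chromosome 17 from 28399094 to 28517527, Angptl4 (ENSMUSG00000002289) on chromosome 17 from 33773750 to 33781830, and Prlr (ENSMUSG00000005268) on chromosome 15 from 10177238 to 10349180. Pkib (ENSMUSG00000019876) lies on chromosome 10 from 57631981 to 57741112 and Unc13b (ENSMUSG00000028456) on chromosome 4 from 43058953 to 43264871.

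Hormone receptors and hormone responsive genes stood higher at dpc16 by camera: 16 of 21 tested members had a log2 change above 0, with a median of 0.42 (adjusted p = 3.81e-07). With an estimated correlation that list had an adjusted p of 0.0643. In it Fkbp5 and Prlr rose over all genes, and 9 members were higher adjusted over the list alone. Socs2, a cytokine signalling inhibitor, stood at 14.2 ± 4.30 against 3.23 ± 3.24 FPKM (adjusted p = 0.146), and Igfbp5, which binds insulin-like growth factors, had a log2 change of 1.59 (adjusted p = 0.141). Basal keratinocyte genes stood slightly higher (14 of 18 above 0, median 0.10, camera adjusted p = 0.0171), with an adjusted p of 0.284 with an estimated correlation. No basal member passed over all genes and 2 passed adjusted over the list alone, among values of 1.47 for Cxcl14 (1259 ± 133 against 483 ± 203 FPKM, adjusted p = 0.117), 0.49 for Cdh3 (0.262) and 0.32 for Col17a1 (0.569).

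Cell cycle lists stood lower in sorted basal cells at dpc16. Of 41 S phase genes 3 lay above 0, with a median of -0.57 (camera adjusted p = 1.76e-13). The S phase list had an adjusted p of 0.235 with an estimated correlation, no member passed over all genes and 9 were lower adjusted over the list alone. The replication helicase genes Mcm3, Mcm6 and Mcm2 had log2 changes of -1.02 (adjusted p = 0.0570), -0.92 (0.156) and -1.84 (0.178), and Gins2 of -0.89 (0.151). Of 57 G2/M genes 2 lay above 0, with a median of -0.56 (camera adjusted p = 9.47e-07), but an adjusted p of 0.907 with an estimated correlation. No G2/M member passed, over all genes or adjusted over the list alone: the mitotic gene Kif23 had a log2 change of -1.23 (adjusted p = 0.321), Gas2l3 of -2.03 (0.373), Ncapd2 of -0.67 (0.545) and Pimreg of -0.92 (0.556).

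Glycolysis and hypoxia genes stood lower too (5 of 25 above 0, median -0.47, camera adjusted p = 0.000197), with an adjusted p of 0.795 with an estimated correlation. None passed over all genes or adjusted over the list alone, with log2 changes of -1.03 for Bnip3 (adjusted p = 0.237), -1.89 for Car9 (0.259), -0.75 for Pkm (0.288) and -0.88 for Tpi1 (0.322). Smooth muscle and pericyte markers had a median of -0.53, 1 of 6 above 0 (camera adjusted p = 0.0116), and an adjusted p of 0.235 with an estimated correlation. Their leading member Acta2, smooth muscle actin, fell from 6.69 ± 2.06 to 1.15 ± 0.0951 FPKM (log2 -1.81, adjusted p = 0.0347) and lost its call in each of the 9 leave-one-out fits (highest 0.215 without WT dpc16 library 2, range 0.0124 to 0.215). In that list 3 members were lower adjusted over the list alone, and Tagln and Mcam had -0.86 (adjusted p = 0.379) and -0.83 (0.388). With a filter of 5 FPKM the smooth muscle list had an adjusted p of 0.291 (range 0.00631 to 0.291).

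Ribosomal protein genes, whose reads can be shared with pseudogenes, had a median of -0.09, 17 of 81 above 0 (camera adjusted p = 0.0189), and an adjusted p of 0.795 with an estimated correlation. None passed over all genes or adjusted over the list alone, as with Rps3 (-0.29, adjusted p = 0.403) and Rps21 (-0.26, 0.416). The call was lost without WT dpc16 library 2 (0.0763), NP library 2 (0.148), NP library 3 (0.0539) and with quantile normalization (0.249), in a range of 0.00379 to 0.249. In all, camera called 7 of 32 lists at dpc16 against NP, 2 higher and 5 lower. With an estimated correlation it called 0, with 7 at the preset value, and fry called 2 of the 7, hormone responsive genes and smooth muscle and pericyte markers. The count of 7 lists became 11 without NP library 1.

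The other lists did not pass camera at dpc16 against NP. Nearest to the threshold stood Langerhans and myeloid markers (median -0.28, adjusted p = 0.0546; Cd74 -1.14, adjusted p = 0.243) and upper hair follicle genes (-0.75, 0.0656; Krt80 -0.83, 0.230, and Sostdc1 -1.14, 0.362). Wnt genes had -0.11 (0.162; Wnt5a -1.22, 0.0816, and Lgr6 -0.96, 0.176), mitochondrially encoded genes 0.29 (0.162) and immediate early genes 0.27 (0.162). Matrix and basement membrane genes had 0.07 (0.214; Fn1 -1.63, 0.141, and Mmp14 0.68, 0.203). Cholesterol synthesis had -0.12 (0.312; Lss -1.17, 0.192, and Fdps -0.78, 0.287), interferon response -0.11 (0.312; Stat2 -0.75, 0.212), endothelial markers 0.07 (0.312; Plvap 1.40, 0.122), YAP targets -0.21 (0.359) and TGF-beta and BMP genes 0.15 (0.519; Bmp2 0.96, 0.396). Mammary luminal genes had a median of -0.71 and a mean of -0.20 while camera pointed up (0.312), with Prlr and Xdh called and Krt8 and Krt18 high in 1 NP library (NP mean 5.62 ± 9.36 and 5.69 ± 9.58 FPKM). Melanocyte markers had 0.10 (0.858), stress keratins and alarmins 0.24 (0.933; Tslp -1.27, 0.172, and Stfa1 3.38, 0.304) and MHC class I genes 0.00 (0.937; H2-D1 -0.67, 0.438).

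Of 25 suprabasal genes Tgm3 alone passed (median -0.15, mean 0.00, adjusted p = 0.933), and Casp14 had -0.52 (0.406). Fibroblast markers had a median of 0.15, a mean of -0.28 and a test pointing down (0.933), and fatty acid and barrier lipid genes a median of 0.00, a mean of -0.07 and a test pointing down (0.937; Cers3 0.67, 0.212, and Scd2 -1.09, 0.272). Lists at an adjusted p of 0.985 at dpc16 against NP were p53 targets (-0.09; Rrm2b 1.06, 0.141), sebaceous gland (0.02), inner root sheath (-0.17), T cell markers (median 0.29, mean -0.06, test down; Cd3g -1.13, 0.328, and Thy1 0.67, 0.783), Notch genes and angiogenic factors. Notch genes had a median of -0.03 and a mean of 0.04 with a test pointing down (Lfng -0.75, 0.327, and Hes1 1.28, 0.629), and angiogenic factors a median of 0.00 with a test pointing up. Bulge genes had a median of -0.16 and a mean of -0.01 with a test pointing up, at the same 0.985. Merkel cell (median -1.48), skeletal muscle (-0.73; Mylpf -1.34, 0.390), adipocyte (-0.37), erythroid (-0.84) and T-box (0.65) lists had too few tested members for camera.

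The comparison of Tbx3 cKO with WT at dpc16 asks what loss of Tbx3 changes in pregnant basal cells. Hpgd, which degrades prostaglandins, rose from 5.19 ± 0.612 to 38.4 ± 4.99 FPKM (SD, n = 3 each). The glucocorticoid-inducible genes Tsc22d3 and Fkbp5 rose, from 82.8 ± 28.9 to 485 ± 224 and from 46.2 ± 9.20 to 203 ± 60.1 FPKM. Krt1, the keratin of differentiating suprabasal cells, fell from 1401 ± 543 to 258 ± 147 FPKM. Slc27a3, a fatty acid transport protein, fell from 159 ± 10.1 to 29.0 ± 7.05, Plxnd1, a semaphorin receptor, from 42.3 ± 6.28 to 4.35 ± 2.55, and Angptl4 from 35.1 ± 8.53 to 4.92 ± 0.763. Igfbp3, which binds insulin-like growth factors, fell from 381 to 135 FPKM on average, while Dst, a linker of hemidesmosomes to keratin filaments, rose from 283 ± 10.2 to 609 ± 99.1.

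By limma with Benjamini-Hochberg adjustment, 247 of 11497 genes passed between cKO and WT dpc16, 141 higher and 106 lower, against 2004 at an unadjusted p under 0.05. The groups did not overlap for 26.2% of genes, where chance gives 10%. Hpgd had a log2 change of 2.67 and Slc27a3 of -2.44, each with an adjusted p of 0.00086. The other large falls that held when any 1 library was left out were Plxnd1 (-3.12, adjusted p = 0.00328), Rerg, a Ras-like growth inhibitor (-2.82, 0.00591), Angptl4 (-2.59, 0.00165) and Krt1 (-2.51, 0.00943). The large rises that held likewise were the amino acid transporter Slc43a1 (2.83, 0.00943), Fam180a (2.98, 0.00444), the zinc finger gene Zfp949 (2.71, 0.00596), the adhesion molecule Mcam (2.54, 0.00452), Tsc22d3 (2.49, 0.00679) and Fkbp5 (2.09, 0.00444). The largest rises, Serpina3n (5.75, 0.00657) and the membrane sialoglycoprotein Gypc (4.28, 0.00165), were taken against WT libraries near 0 (0.380 ± 0.657 and 0.0420 FPKM on average), so their size depends on the pseudocount. Serpina3n stood at 272, 36.9 and 31.4 FPKM in the 3 cKO libraries, and reads of the Serpina3 and Stfa families can be shared between paralogs. For each gene in this paragraph all 3 cKO libraries lay on 1 side of all 3 WT dpc16 libraries.

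Further large changes in cKO against WT dpc16 lost their calls in leave-one-out fits. Stfa3 lost its call in 8 such fits, Drc1 in 6, Adam8 in 5, and Angptl7, Gadl1 and Pglyrp4 in 4 each. Serpina3j, Gpnmb and Car12 lost theirs in 3 each, Spock2 in 2 and Klk8 in 1. The fit with the highest adjusted p is given for each. Without cKO library 1 the adjusted p was 0.0787 for Angptl7 (log2 3.09, main adjusted p = 0.0172, range 0.00285 to 0.0787), 0.0733 for Spock2 (2.74, 0.0172, range 0.00812 to 0.0733), 0.162 for Stfa3 (-3.30, 0.0447, range 0.00736 to 0.162) and 0.101 for Gadl1 (-2.84, 0.0289, range 0.0265 to 0.101). It was also 0.124 for Drc1 (-2.47, 0.0332, range 0.00749 to 0.124), 0.0835 for the protease Adam8 (-2.23, 0.0192, range 0.00448 to 0.0835) and 0.0685 for Pglyrp4 (-2.20, 0.0172, range 0.00850 to 0.0685). Without WT dpc16 library 2 it was 0.0950 for Serpina3j (3.00, 0.0260, range 0.0151 to 0.0950), 0.0674 for the glycoprotein Gpnmb (2.65, 0.0172, range 0.0111 to 0.0674) and 0.0526 for the peptidase Klk8 (-2.16, 0.00987, range 0.00749 to 0.0526). Without WT dpc16 library 3 it was 0.0640 for the carbonic anhydrase Car12 (-2.16, 0.0156, range 0.0108 to 0.0640). Of 46 named genes called in this comparison, 18 held when any 1 library was left out. The count of 247 became 65, 41 and 57 without WT dpc16 libraries 1, 2 and 3, 156 without NP library 2, 60 and 83 without cKO libraries 1 and 2, and 406 without cKO library 3. It was 87 without the filter on low FPKM, 160 without a trend and 118 in a fit of the 6 libraries compared.

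On mm10, Hpgd (ENSMUSG00000031613) lies on chromosome 8 from 56294585 to 56321043, Slc27a3 (ENSMUSG00000027932) on chromosome 3 from 90385239 to 90389938, and Plxnd1 (ENSMUSG00000030123) on chromosome 6 from 115954811 to 115995005. Krt1 (ENSMUSG00000046834) lies on chromosome 15 from 101845426 to 101850794, Tsc22d3 (ENSMUSG00000031431) on chromosome X from 140539528 to 140600659, and Rerg (ENSMUSG00000030222) on chromosome 6 from 137054825 to 137170497. Mcam (ENSMUSG00000032135) lies on chromosome 9 from 44134469 to 44142727 and Slc43a1 (ENSMUSG00000027075) on chromosome 2 from 84838850 to 84863594.

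Among fixed lists, ribosomal protein genes stood higher in cKO than in WT dpc16: 77 of 81 lay above 0, with a median of 0.25 (camera adjusted p = 2.66e-14). That list had an adjusted p of 0.157 with an estimated correlation, and no member passed over all genes or adjusted over the list alone (Rps25 0.36, adjusted p = 0.0709; Rpl12 0.36, 0.0776; Rps19 0.43, 0.0936; Rpl4 0.34, 0.0985). Genes of p53 targets and cell cycle inhibitors had a median of 0.38, 16 of 20 above 0 (camera adjusted p = 0.0292), and an adjusted p of 0.878 with an estimated correlation. None of them passed over all genes and 2 were higher adjusted over the list alone (Trp53inp1 1.40, adjusted p = 0.0553; Cdkn1b 0.73, 0.0555; Ccng1 0.81, 0.164). The p53 call was lost without WT dpc16 library 3 (0.0538) and cKO library 2 (0.187), in a range of 0.00166 to 0.187.

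YAP and stretch targets had a median of 0.36 in cKO against WT dpc16, 12 of 16 above 0 (camera adjusted p = 0.0362), and an adjusted p of 0.878 with an estimated correlation. In that list 4 members rose, over all genes and adjusted over the list alone: Nt5e (1.53, adjusted p = 0.0194), Crim1 (1.16, 0.0202), Amotl2 (0.85, 0.0381) and the matricellular gene Ctgf (1.93, 0.0419). Each of these 4 calls was lost without WT dpc16 library 1, 2 or 3, with adjusted p up to 0.0748 (Nt5e, range 0.0178 to 0.0748), 0.0848 (Crim1, range 0.00749 to 0.0848), 0.140 (Amotl2, range 0.0317 to 0.140) and 0.146 (Ctgf without cKO library 1, range 0.0284 to 0.146). The YAP list missed the threshold without WT dpc16 library 3 (0.140), NP library 3 (0.0654), cKO library 1 (0.0545) and with a filter of 5 FPKM (0.202), in a range of 0.0103 to 0.202. Wnt genes had a median of -0.24, 7 of 19 above 0 (camera adjusted p = 0.0292), and an adjusted p of 0.878 with an estimated correlation. The ligand genes Wnt3 (-0.92, adjusted p = 0.0279) and Wnt6 (-0.89, 0.0381) fell, beside Wnt10b (-0.83, 0.0630) and Wnt4 (-1.05, 0.0757), and 5 members were lower and 1 higher adjusted over the list alone. Wnt3 missed the threshold in 5 leave-one-out fits (up to 0.103 without cKO library 1, range 0.0210 to 0.103) and in 1 other setting. Wnt6 missed the threshold in 6 such fits (up to 0.148 without WT dpc16 library 2, range 0.0317 to 0.148) and in 4 other settings. The Wnt list missed it without WT dpc16 library 1 (0.0517) and with a filter of 5 FPKM (0.0714), in a range of 0.0107 to 0.0714. In all, 4 lists passed, 3 higher and 1 lower, with 0 by an estimated correlation, which left the 4 at the preset value uncalled. By fry 2 lists passed, ribosomal protein genes and fibroblast markers, and only the first is among the 4. The count of 4 lists became 7 without WT dpc16 library 1 and 7 without cKO library 3.

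Hormone responsive genes went both ways in cKO against WT dpc16: 4 rose, 3 fell and 14 did not pass, while the list's median was -0.06, its mean 0.17 and its test pointed up (camera adjusted p = 0.989). Adjusted over the list alone 6 were higher and 5 lower. Fkbp5 and Tsc22d3 rose, while Igfbp3 (-1.50, adjusted p = 0.00608), Igfbp5 (-2.41, 0.00943) and Prlr (-1.11, 0.0172) fell. The Prlr call was lost without any 1 of WT dpc16 libraries 1, 2 and 3 and cKO library 1 (up to 0.0772 without WT dpc16 library 1, range 0.0127 to 0.0772). Of 25 suprabasal genes Krt1 and Grhl3, a transcription factor of barrier formation (-1.39, 0.00657), fell and 6 were lower adjusted over the list alone (median -0.20, camera adjusted p = 0.269). Of 18 basal genes Dst rose (1.09, 0.00608) and Krt14 had -0.64 (0.143), with a list median of -0.05 (camera adjusted p = 0.636).

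Stress and cell type lists did not pass camera in cKO against WT dpc16. Immediate early genes had a median of 0.46 (adjusted p = 0.471), with median FPKM of 717, 293 and 127 in the 3 cKO and 373, 232 and 58.6 in the 3 WT dpc16 libraries. Langerhans and myeloid markers had 0.43 (0.471; Cd74 0.72, 0.262), T cell markers -0.36 (0.471; Thy1 -1.03, 0.375), endothelial -0.09 (0.526), sebaceous a median of -0.09, a mean of 0.05 and a test pointing up (0.936), inner root sheath 0.07 with a test pointing down (0.989) and melanocyte -0.11 with a test pointing up (0.968). Of 15 fibroblast markers 3 were tested, with a median of -1.46 (0.410; 0.878 with an estimated correlation, but 0.0208 and lower by fry), 2 lower and 1 higher adjusted over the list alone: Sparc fell (-1.68, 0.0106; 0.0554 without WT dpc16 library 2, range 0.00874 to 0.0554), Col6a1 had -1.46 (0.0730) and Fn1 1.31 (0.0771). Smooth muscle and pericyte markers had 0.09 (0.989), where Mcam rose and the receptor gene Notch3 fell (-1.06, 0.0209). The Notch3 call was lost in 5 leave-one-out fits (up to 0.0820 without WT dpc16 library 3, range 0.0193 to 0.0820). Upper follicle genes had 0.29 (0.631; Krt80 0.86, 0.0711), bulge genes 0.15 (0.556; Fst 1.03, 0.158) and mammary luminal genes a median of 0.03, a mean of -0.02 and a test pointing up (0.989). Merkel cell (0.13), skeletal muscle (-0.85), adipocyte (0.98; Lpl 0.98, 0.122), erythroid (-0.04) and T-box (-0.92) lists were too small for camera.

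Pathway and metabolic lists that did not pass in cKO against WT dpc16 were glycolysis and hypoxia (median -0.20, mean 0.02, test down, adjusted p = 0.556), with the mitophagy receptor gene Bnip3 rising (1.85, 0.0119; 0.0573 without WT dpc16 library 2, range 0.00207 to 0.0573), and cholesterol synthesis (-0.20, 0.320). In the latter Sc5d fell (-0.93, 0.0418; 0.147 without WT dpc16 library 2, range 0.0352 to 0.147) and Hmgcs1 had 0.56 (0.0680). Fatty acid and barrier lipid genes had -0.13 (0.556), with Elovl4, an elongase of barrier lipids, falling (-1.47, 0.0255; 0.0772 without WT dpc16 library 1, range 0.0211 to 0.0822) and Acer1 at -1.36 (0.0660). Notch genes had 0.19 (0.631), with the receptor gene Notch3 falling and the ligand Dll1 rising (0.92, 0.0470; 0.166 without cKO library 1, range 0.0217 to 0.166). TGF-beta genes had 0.05 (0.471), with Tgfbi rising (0.65, 0.0360; 0.147 without WT dpc16 library 2, range 0.0298 to 0.147), and stress keratins and alarmins -0.07 (0.936), with Stfa3 falling and the cytokine Tslp rising (1.40, 0.0420; 0.144 without WT dpc16 library 1, range 0.0312 to 0.144). The call was lost in 9 leave-one-out fits for Tslp, 7 each for Tgfbi and Sc5d, 6 for Dll1, 4 for Elovl4 and 2 for Bnip3. S phase genes had a median of -0.01, a mean of 0.06 and a test pointing up (0.854), and G2/M genes 0.14 (0.471). Mitochondrially encoded genes had -0.29 (0.471), interferon response 0.18 (0.471), MHC class I 0.09 (0.526), angiogenic factors -0.13 (0.526; Pdgfb -0.96, 0.0514), and matrix genes 0.17 (0.857; Col7a1 -0.92, 0.0707, and Timp3 1.49, 0.0723).

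**Figure D2:**
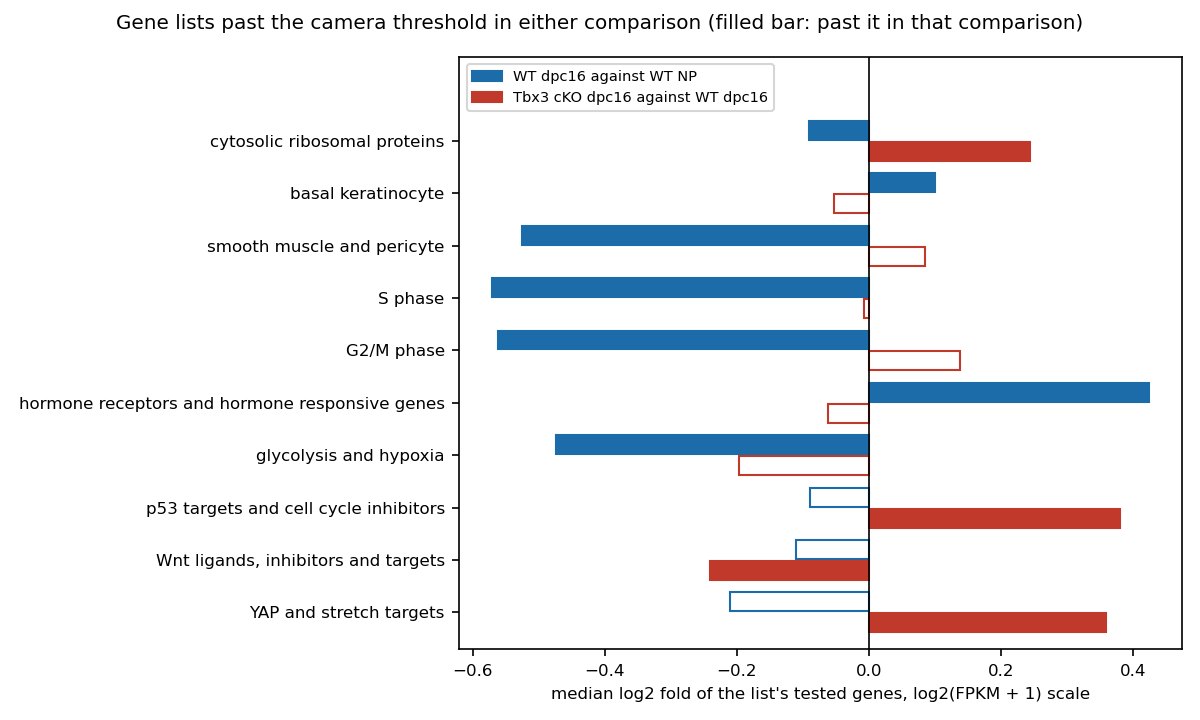
Median log2 change of gene lists past the camera threshold in WT dpc16 against NP or in cKO against WT dpc16, with filled bars where the list passed in that comparison. S phase genes have a median of -0.57 in the first and -0.01 in the second, and ribosomal protein genes -0.09 and 0.25.

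Whether genes changed by pregnancy go the other way in cKO was asked across both contrasts. Of 12 genes higher in pregnancy, 6 fell in cKO: Angptl4 (-2.59, adjusted p = 0.00165), Grk3 (-2.21, 0.00679), Il4ra (-1.78, 0.00943), Prlr, Deptor (-1.05, 0.0406) and Drc1, where independent lists of calls give 0.111. Pkib, lower in pregnancy, rose in cKO (2.01, 0.00987; independent lists 0.0368). Fkbp5 and Xdh (0.74, 0.025) rose in both, where independent lists give 0.147; the Xdh call in cKO was lost without any 1 of WT dpc16 libraries 1, 2 and 3 and cKO libraries 1 and 2 (up to 0.110 without WT dpc16 library 1, range 0.0203 to 0.110). Other settings were not run for Grk3, Il4ra, Deptor and Pkib in this contrast. Tgm3 (-0.58, 0.529), Serpina3b (0.02, 0.991) and Pyy (-0.95, 0.0907) did not pass in cKO against WT dpc16. The contrasts share the WT dpc16 libraries with opposite sign, which favours opposite changes. In 100 simulated sets with no group effect 0 such overlaps arose, but such sets are expected to hold few calls and do not measure this, so part of the overlap may come from the shared libraries. Across all 11497 genes Pearson's r was -0.256 and Spearman's rho -0.187, over genes that are not independent replicates. Simulation without any effect gave -0.499 (SD 0.0143) and -0.463. Real changes in either contrast add spread that the simulation lacks and move r and rho towards 0, so that gap does not measure reversal. The covariance was -0.0509 against a simulated -0.0536, an excess of 0.00268 with a simulated SD of 0.00239, and a negative excess of -0.00739 with a moderated spread and of -0.0101 with the WT spread. Leaving out 1 library gave -0.00179 (NP library 1), -0.000653 (NP library 3) and -0.00427 (cKO library 1), so no shared effect across all genes was read from it.

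The secondary comparison sets cKO at dpc16 beside WT NP. Fkbp5 stood at 203 ± 60.1 against 6.26 ± 1.30 FPKM (log2 4.79, adjusted p = 1.81e-05). Serpina3n (5.33, 0.00671), Serpina3j (4.58, 0.00373) and Gypc (4.32, 0.00086) rose from NP levels under 1 FPKM, so the size depends on the pseudocount. Krt1 (-2.53, 0.00671), Slc27a3 (-2.41, 0.000504), the adenylate kinase Ak1 (-2.27, 0.0112) and the suprabasal keratin Krt77 (-2.24, 0.0127) fell, as did Hpgds, a prostaglandin D synthase (-2.48, 0.0407). Krt77 missed the threshold without cKO library 1 (0.0537, range 0.00149 to 0.0537). Hpgds missed the threshold in 7 leave-one-out fits (up to 0.117 without NP library 2, range 0.0228 to 0.117). In all 651 genes passed limma with Benjamini-Hochberg adjustment, 317 higher and 334 lower, against 2734 at an unadjusted p under 0.05, with no overlap of groups for 26.4% of genes, where chance gives 10%. The count became 387 and 332 without WT dpc16 libraries 1 and 2, 217 and 270 without NP libraries 2 and 3, 118 and 314 without cKO libraries 1 and 2, 314 without the filter, 427 without a trend, 167 in a fit of the 6 libraries compared and 368 at 2-fold. Tbx3 had a log2 change of -0.96 (adjusted p = 0.101).

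In cKO against NP camera called 9 lists, 4 higher and 5 lower, with 0 by an estimated correlation. By fry 6 passed: ribosomal protein, hormone responsive, S phase and Wnt genes, which camera called, and fibroblast and smooth muscle and pericyte markers (both lower), which it did not. By camera, higher were ribosomal protein genes (median 0.16, adjusted p = 3.78e-06; adjusted p = 0.342 with an estimated correlation), hormone responsive genes (0.53, 0.000657; 0.326), p53 targets (0.31, 0.0429; 0.628) and immediate early genes (0.58, 0.0429; 0.887). Lower were S phase genes (-0.48, 4.09e-06; 0.574), Wnt genes (-0.45, 0.000657; 0.342), glycolysis and hypoxia genes (-0.68, 0.00538; 0.707), cholesterol synthesis (-0.53, 0.0265; 0.628) and G2/M genes (-0.34, 0.0307; 0.887). The last value in each bracket is the adjusted p with an estimated correlation. Adjusted over the list alone, 9 hormone responsive genes were higher and 2 lower, 3 p53 and 1 ribosomal protein genes higher and 0 lower, 8 S phase genes lower and 0 higher, 7 Wnt genes lower and 1 higher, 12 glycolysis and hypoxia genes lower and 3 higher, 4 cholesterol synthesis genes lower and 1 higher, 1 immediate early gene lower and 0 higher, and no G2/M gene passed.

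The single-cell libraries ask how epidermal cells differ between NP, dpc16, dpp6 and dpp40 skin. Barcodes numbered 6635, 12984, 9351 and 8716, of which 6491, 12853, 9031 and 8552 cells were kept, beside stated numbers of 6485, 12846, 9029 and 8552. Kept cells had median depths of 4709, 4448, 5014 and 5638 UMIs and medians of 1519, 1455, 1590 and 1675 genes. With 1 library per state, intervals cover counting error only. Basal-like keratinocytes made up 17.9% (95% interval 17.01% to 18.9%) of NP cells, 35.2% (34.4% to 36.1%) at dpc16, 15.4% (14.7% to 16.2%) at dpp6 and 21.9% (21.1% to 22.8%) at dpp40. Suprabasal-like cells made up 21.3%, 20.7%, 14.6% and 20.3% in that order, upper follicle-like cells 15.1%, 10.6%, 15.1% and 14.3%, bulge-like cells 6.25%, 1.55%, 13.9% and 6.42%, and sebaceous-like cells 2.28%, 1.67%, 3.03% and 1.95%. T cell-like cells made up 0.739%, 0.957%, 0.941% and 0.690% and Langerhans-like cells 1.46%, 1.43%, 2.25% and 1.16%. Unnamed clusters held 34.8%, 27.9%, 34.3% and 33.2%. Of the basal-like clusters, 1 that is led by the stress genes Fos, Cyr61, Dusp1 and Jun held 2159 of 4528 basal-like cells at dpc16 and 295 of 1164 in NP. A further one is led by Ier3, Atf3 and Junb, and a suprabasal-like one also by Fosl1 and Serpinb2. Stress genes differed between libraries (1.06%, 1.33%, 1.28% and 1.52% of basal-like UMIs), so the order of basal-like shares is not read as a change in cell numbers.

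Tbx3 in basal-like cells stood at 3.59 CPM in NP (95% interval 2.16 to 5.61), 10.4 at dpc16 (9.03 to 11.97), 4.42 at dpp6 (2.98 to 6.31) and 2.68 at dpp40 (1.76 to 3.89). The mice carry Tbx3creERT2, and how that allele affects the count is not given in the sources used here. Over all cells Tbx3 stood at 4.35 (3.73 to 5.05), 12.6 (11.8 to 13.4), 3.86 and 2.59 CPM, and in suprabasal-like cells at 3.95, 18.2 (16.6 to 19.97), 5.67 and 2.59. In T cell-like cells, taken as a measure of background, dpc16 had 12.2 CPM (5.84 to 22.4), and in Langerhans-like cells 8.44 (4.05 to 15.5). Keratin 14 transcripts at dpc16 were at 4561 CPM in T cell-like against 8852 in basal-like cells. At dpc16 4.15% of basal-like cells (median depth 3810.5 UMIs) had a Tbx3 UMI, beside 7.32% of T cell-like (5129 UMIs) and 4.89% of Langerhans-like cells (5284 UMIs), so the share in basal-like cells is not told apart from background. After thinning to 2000 UMIs, 3.88% of suprabasal-like cells (3.18% to 4.69%) had one at dpc16, against 0.543% of Langerhans-like (0.0138% to 2.99%) and 1.63% of T cell-like cells (0.198% to 5.75%). Thinned basal-like shares were 0.601%, 2.19%, 1.01% and 0.426%, and averaged over draws 0.733%, 2.06%, 1.004% and 0.540%.

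Basal-like cells with at least 3 G2/M UMIs after thinning made up 38.2%, 46.2%, 42.3% and 44.6% in NP, dpc16, dpp6 and dpp40. The G2/M list itself summed to 1948, 1666, 1723 and 1950 CPM, which is an opposite order for NP and dpc16. T cell-like cells had shares of 45.8% to 52.8% and suprabasal-like cells of 47.8% to 52.4%, so this measure was not specific to cycling basal cells and no order of cycling is read from it.

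In basal-like cells Pyy stood at 37.2 CPM in NP (95% interval 32.2 to 42.8), 198 at dpc16 (192 to 204), 198 at dpp6 and 21.8 at dpp40. Tgm3 stood at 41.0 (35.7 to 46.9), 201 (195 to 208), 41.4 and 17.4 CPM, and Thy1, a surface glycoprotein that is also on the T cell list, at 47.3, 190, 37.0 and 35.8. Mmp2, a gelatinase, had a log2 difference of dpc16 minus NP of 1.94, Abcg2, a transporter of side population cells, 1.45, Mid1, a ubiquitin ligase, 1.22, and the multigene family members Serpina3b and Stfa3 1.62 and 1.48. The transcripts Gm26917 (1.93) and Gm17056 (1.57) complete the higher genes. Pkib stood at 116 CPM in NP (107 to 125), 17.3 at dpc16 (15.4 to 19.2), 78.3 at dpp6 and 107 at dpp40, and the Wnt ligand gene Wnt16 at 53.9 (47.8 to 60.5), 9.54 (8.21 to 11.03), 23.4 and 37.8. Txnip, an inhibitor of thioredoxin, stood at 459, 164, 252 and 359, and the keratinocyte chemokine Ccl27a, a symbol shared by several IDs, at 4763, 1877, 3903 and 4189. The other lower genes were Pik3ip1 (-1.43), Ly6c1 (-1.42), Crip1 (-1.30), the alcohol dehydrogenase Adh7 (-1.28), Lockd (-1.23) and Gm10263 (-1.16). All named genes have intervals of the libraries compared that do not overlap. Free RNA from other cells was not separated from expression in basal-like cells for any of them, including Tgm3, which is on the suprabasal list.

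**Figure D3:**
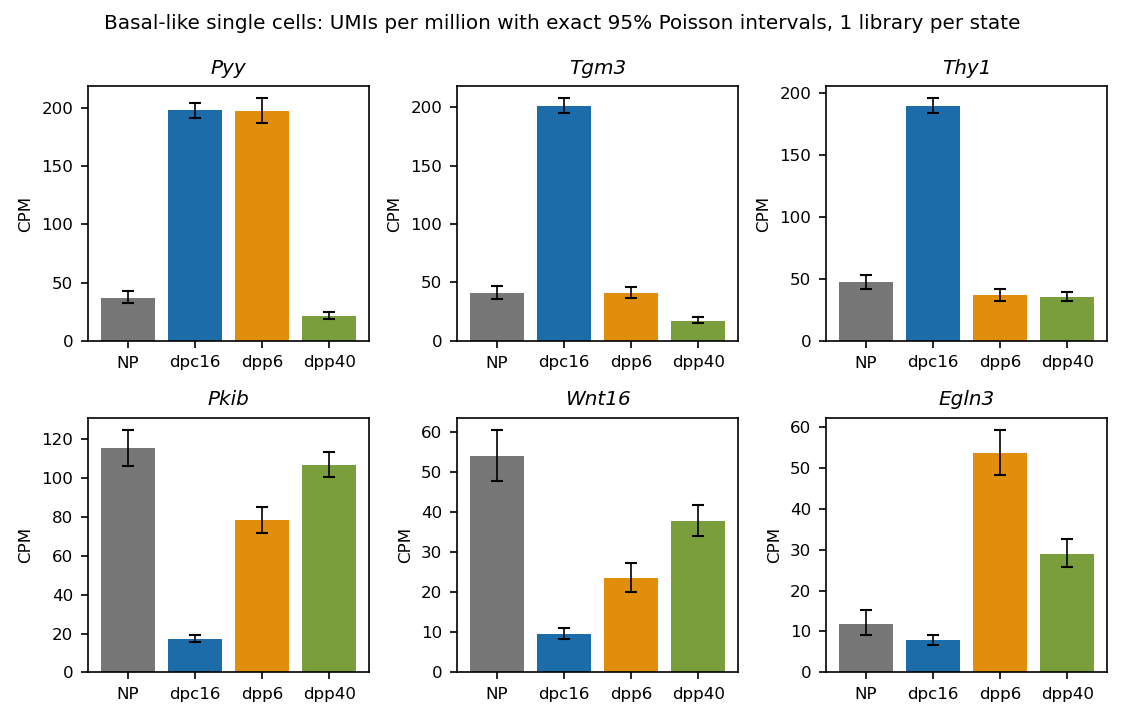
CPM (scaled UMI counts) of 6 genes in basal-like cells of the 4 single-cell libraries, 1 per state, with exact 95% Poisson intervals as bars. Pkib stands at 116, 17.3, 78.3 and 107 CPM in NP, dpc16, dpp6 and dpp40.

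After birth several of these values lay near NP again. Against dpc16, basal-like cells at dpp6 had higher Egln3, an oxygen-sensing hydroxylase (7.82 to 53.5 CPM, log2 2.19), Pkib (1.90), the chemokine Ccl20 (12.2 to 54.1 CPM, 1.78), Bnip3 (33.9 to 97.4 CPM, 1.40), the clock-related repressor Bhlhe40 (1.34) and Pik3ip1 (1.24). They had lower Serpina3b (55.1 to 5.31 CPM, -2.54), Thy1 (-2.21), Tgm3 (-2.15), Mid1 (-2.00) and Mmp2 (-1.67). At dpp40 against NP, basal-like cells had more of the clock gene Dbp (45.0 to 144 CPM, log2 1.58), the heat shock gene Hspa1a (255 to 728 CPM, 1.495), Ccl20 (1.35), Gadd45b (1.11), Thbs1 (1.09) and Hes1 (1.06). They had less Gm8797 (-1.35), Gm10020 (-1.27) and Il22ra2, a soluble receptor of interleukin 22 (83.7 to 35.7 CPM, -1.12). Also lower were Gm10076 (-1.04), the metallothionein Mt4 (-0.94) and Rdh12 (-0.90). Hspa1a is on the stress list, which took 1.06% of basal-like UMIs in NP and 1.52% at dpp40. Thbs1 and Hes1 are leading genes of unnamed cluster 5, beside the stress genes Atf3, Fosl1 and Dusp1. With 1 library per state, the dpp40 differences were not separated from dissociation stress or other differences between libraries.

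Gene lists were placed among 10000 random lists of like expression, as a description of these libraries. At dpc16 against NP, hormone responsive genes had a median of 0.32 with 13 of 18 above 0 (percentile 100), S phase genes 0.32 with 26 of 27 (percentile 100) and G2/M genes -0.53 with 5 of 38 (percentile 0). Glycolysis and hypoxia genes had 0.09 with 16 of 22 above 0 (percentile 91.44), while their median in the bulk libraries was -0.47. The S phase direction is also opposite to that in the bulk libraries. Unnamed cluster 9, led by the cycling genes Ube2c, Top2a and Birc5, with 339 cells in NP and 507 at dpc16, is outside the basal-like sums. Cluster 14, led by the cycling genes Cenpa, Hmgb2, Cks2 and Stmn1 with 0 basal markers among its leading 10, is counted as basal-like and held 164 of 1164 such cells in NP and 337 of 4528 at dpc16, so the cell cycle medians were not separated from the mix of clusters. Immediate early genes had 0.33 (percentile 100), where 8 members are leading genes of basal-like clusters, and MHC class I -0.25 (0.09). Upper follicle genes had -0.42 (0.02), bulge genes -0.39 (0.06), sebaceous genes -0.37 (0.69) and erythroid genes -2.07 (0). Transcripts of other cell types in these droplets, at every stage, were not told apart from free RNA and are not read as changes in basal-like cells. At dpp6 against dpc16 glycolysis and hypoxia genes had 0.66 with 21 of 22 above 0 (percentile 100), upper follicle genes 0.45 (100), p53 targets 0.23 (99.89), bulge genes 0.27 (99.61), MHC class I 0.20 (99.58), sebaceous genes 0.36 (99.22), hormone responsive genes -0.20 (0), erythroid genes -1.58 (0), S phase genes -0.11 (0.13) and ribosomal protein genes -0.05 (1.56). At dpp40 against NP glycolysis and hypoxia genes had 0.63 with 21 of 22 above 0, immediate early genes 0.45, S phase genes 0.30 and cholesterol synthesis 0.20 (each at percentile 100), upper follicle genes 0.26 (99.99), basal keratinocyte genes -0.14 (0.72) and erythroid genes -4.07 (0). The other medians and percentiles lay between 2 and 99 in each comparison.

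Both assays share the contrast of dpc16 with NP. Across 4710 genes their log2 changes had a Spearman rho of 0.205 and a Pearson r of 0.344, over genes that are not independent replicates. All 10 genes called in bulk and measured in basal-like cells went the same way there, among them Deptor, Fkbp5, Il4ra, Pkib, Prlr, Pyy, Serpina3b, Tgm3 and Xdh. Over all cells of each library, rho was 0.247 and r was 0.380 across 4828 genes, and 9 of 9 such genes went the same way.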

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

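The tests of the EGFP pattern were chosen after the result was seen. Transcripts of EGFP, the reporter gene that the submitters added to the reference, were not part of the planned comparisons and are flagged because these data were otherwise left unanalysed. In clusters 16 and 22, which are suprabasal-like and led by the cornified layer genes Lor, Flg2 and the Lce family, 22.3% of NP, 23.2% of dpc16, 20.98% of dpp6 and 16.2% of dpp40 cells held an EGFP UMI. In CPM that is 23.8 (95% interval 18.2 to 30.5), 19.0 (13.7 to 25.8), 18.4 (13.3 to 24.9) and 13.0 (10.0 to 16.5), beside 1.32, 1.09, 2.06 and 1.19 in basal-like cells. Tbx3 itself stood at 1.17, 6.97, 2.63 and 1.20 CPM in the same clusters. No library without the transgene is among those analysed.

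Free RNA could put EGFP into these cells, but EGFP CPM lay above the upper limit for pooled T cell-like and Langerhans-like cells in 4 of 4 libraries. Those pooled cells held 1, 4, 6 and 2 EGFP UMIs in NP, dpc16, dpp6 and dpp40. Free RNA at their level thus does not account for these values, while a higher level in droplets of clusters 16 and 22 was not tested. Depth of the cells could raise the share, because median depth there was 11750 to 15960 UMIs, but CPM, which is relative to depth, had intervals above those of basal-like cells in every library, and the share expected over random thinning to 2000 UMIs was at least 9.01 times that of basal-like cells, so depth was excluded as the whole cause. A single draw of thinning gave less at dpp40 (2.03% beside 0.480%, with overlapping intervals). Reporter transcripts that outlast Tbx3 expression, or priming within a transcript of the cornified layer that resembles the added sequence, could each give this pattern, and neither was tested. Reads from a library of the same age without R26H2B-EGFP would separate them.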

How the results depend on the processing

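The block by column number, the doublet removal, the naming pseudocounts and both other spreads of the reversal were chosen after seeing the data, and leave-one-out fits keep 2 or 3 libraries per group. The title numbers could not be assigned to columns, so the planned block by them was not run. Columns of 1 number are not known to share more than that number. The r of their deviations from the group means was 0.312, 0.0692 and 0.357 between WT dpc16 and cKO. For pairs with NP it was -0.212 to 0.0385. Immediate early medians fell with column number in both WT dpc16 and cKO, and whether these columns share an order or batch was not tested. A block by column number gave 10, 202 and 553 genes and the same 7 and 4 lists. With it adjusted p rose past 0.05 (0.0509 to 0.142) for the following genes. They were Xdh, Pkib, Unc13b and Acta2 in WT dpc16 against NP and Hpgds in cKO against NP. In cKO against WT dpc16 they were Xdh, Wnt6, Dll1, Amotl2, Ctgf and Sc5d. This is not read as a weaker effect, and no other call of a list or rule-named gene was lost where it was run. In WT dpc16 against NP all 10 calls were among the 15, and 10 of the 14 rule-named genes kept theirs, so Grk3 lost its call. Genes called in WT dpc16 against NP (15) were 9 without the filter on low FPKM and 5 to 15 with 1 library left out. In cKO against WT dpc16 (247) they were 87 without the filter, 160 in eBayes without trend, 118 in a fit of only the 6 libraries compared and 41 to 406 with 1 library left out. In cKO against NP (651) they were 314, 427, 167, 368 with a 2-fold minimum, and 118 to 736. Leaving out 1 library lowered some counts and raised others; the cause was not tested for any of these settings. Gene lists called by camera (7 and 4) were 0 and 0 with an estimated correlation and 2 and 2 with fry, of which 2 and 1 were lists that camera called, and 6 to 11 and 3 to 7 with 1 library left out. The reversal excess (0.00268) changed sign without NP library 1 (-0.00179), without NP library 3 (-0.000653) and without cKO library 1 (-0.00427), in a range up to 0.0219. It was -0.00739 with a moderated spread and -0.0101 with the spread of the WT dpc16 libraries alone. The ratio of basal-like shares, dpc16 over NP (1.96), was 2.13 at Leiden resolution 0.5, 1.84 at resolution 2.0, 1.84 at 5% mitochondrial UMIs and 1.41 at a naming pseudocount of 20 CPM. The ratio for cell cycle transcripts (1.21) was 1.39 at resolution 0.5, 1.11 at resolution 2.0, 1.07 not thinned, 1.06 thinned to 1000 UMIs, 1.09 with at least 2 UMIs and 1.11 with at least 5. The ratio for a Tbx3 UMI (3.64) lay between 1.73 and 5.15. Agreement of bulk and single-cell changes (0.205) was 0.247 over all cells; the cause was not tested. Of 695 settings of single genes 614 left the call and 81 lost it, and of 630 leave-one-out fits 438 left it and 192 lost it; for single lists 40 of 44 and 90 of 99 left it. No rule-named gene changed direction where the settings were run.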

Other observations

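The tests of the splits were chosen after the result was seen, while the tests of the glucocorticoid pattern were written before their values were seen, though that pattern was picked from called genes and it was known that none of the further genes was called. Unc13b in cKO stood near its WT dpc16 value (3.59 FPKM beside 4.29, with 12.1 in NP), and so did Serpina3b (76.4 beside 69.6, with 7.40 in NP), whereas Angptl4 (4.92 beside 5.33 in NP) and Il4ra (22.5 beside 22.9) stood near their NP values.

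In single cells, of the genes named as higher at dpc16 than in NP, only Pyy stayed at its dpc16 value at dpp6 (198 CPM in both). Tgm3 (41.4) and Thy1 (37.0) were back near NP. Of the genes named as lower, Crip1, Ly6c1 and Gm10263 stayed near their dpc16 values at dpp6, with overlapping intervals. Crip1 stood at 134 CPM at dpc16 and 135 at dpp6 (337 in NP), and Gm10263 at 40.8 and 41.7 (96.97 in NP). The other genes named as lower stood higher at dpp6 than at dpc16. Egln3 and Bnip3, both targets of hypoxia, were at 53.5 and 97.4 CPM at dpp6.

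Fkbp5, Tsc22d3, Sgk1 and Klf15 rose in cKO against WT dpc16 (log2 2.09, 2.49, 1.65 and 1.80), which may reflect a glucocorticoid response, dissociation stress or reduced insulin signalling through FOXO. With the median of the stress list as a linear covariate 4 of 4 stayed past the limma threshold (1.95, 2.26, 1.41 and 1.54). All calls went from 247 to 198, of which 155 were among the 247. A linear effect of that median thus did not remove these 4 calls. A single covariate, tried on genes picked as called, cannot exclude dissociation stress. By the rule set beforehand a glucocorticoid response fits, since 8 further target genes that were not called had a median of 0.81. Of these 8 of 8 lay above 0, at percentile 99.99 of 10000 random lists, which treat genes as independent. With the stress covariate their median was 0.40 with 7 of 8 above 0, below the median that the rule asked for. The response was thus not separated from stress, and Angptl4, also inducible by glucocorticoids, fell. Reduced insulin signalling through FOXO could not be told apart: its 8 genes had a median of 0.27, 7 of 8 above 0 (percentile 96.4), with Gadd45a at -1.39. With the covariate their median was 0.26 with 6 of 8 above 0. Tamoxifen or corticosterone status, which may differ with genotype, would be tested by serum hormone values and tamoxifen-treated WT mice.

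Gene counts may reflect the grouping or structure among samples. Of 10 splits of the 6 libraries into 3 and 3, only the real one gave as many genes, in each of the 3 comparisons. The real counts were 15, 247 and 651, and the highest others 0, 0 and 1. Every other split mixes the real groups, so a real difference enters the spread and lowers the calls. Few calls there do not exclude a structure of the samples, and 10 splits are too few for a share under 0.05. For gene lists 5 of 10 splits gave at least the real 7 in WT dpc16 against NP (highest other 10) and 10 of 10 gave at least the real 4 in cKO against WT dpc16 (highest other 12). The larger list counts of other splits point to a structure of the samples or to correlation between the genes of a list, since an estimated correlation gave 0 and 0 lists in place of 7 and 4; the cause was not tested.

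S phase genes went down in sorted cells (median -0.57) and up in single cells (0.32), while G2/M genes had medians below 0 in both (-0.56 and -0.53). The single-cell values include cluster 14, led by cycling genes, with 164 of 1164 basal-like cells in NP and 337 of 4528 at dpc16. They leave out unnamed cluster 9, also led by cycling genes, with 339 cells in NP and 507 at dpc16. The medians are therefore not read as agreement or disagreement within cells. The cause was not tested.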
